A study of Mus musculus with 18 samples.

How the data were processed

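Total RNA from liver and kidney of mice given saline or GalN was labelled with the One-Cycle protocol and hybridised to Affymetrix mouse genome arrays, per the labels' protocols. The organs were perfused in situ before RNA was taken. The label field lists a Cy3 dye although the platform is a single-colour Affymetrix array. The protocol's wording on RNA of 3 mice can be read as pooling. The sample titles give 1 array per letter (A, B and C) in each group. Arrays were treated as single animals, which is an assumption. Whether the same letter in liver and kidney is the same mouse is not stated. Quantitative PCR is also described and was not used here.

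The deposited table holds 1 value per probe set and array, and the authors computed these as log2 gcRMA values, per the labels and the submitters' processing notes. The version of GCRMA is not stated. The values were checked to be on the log2 scale, with a lowest value of 2.21, and were used as deposited. The table has 45101 probe sets, of which 64 control sets were left out of the gene tests. Of the sets left, 34945 are named for 1 gene, 932 for several genes and 9160 for none. The Entrez identifier of 34741 of the sets named for 1 gene was found in the mouse gene reference, and 0 symbols changed. No set is named for Gapdh or Ren1 alone, and sets named for several genes were not used for them. Gapdh was therefore read only from the array's control sets. The set with the highest mean over the 18 arrays stood for each gene, which gave 18193 genes.

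Groups were taken from the labels: sham, 24 h and 48 h in each of the tissues, with 3 arrays each. A gene was tested in a tissue if its value was above the array median (percentile 50) in at least 3 of the 9 arrays of that tissue. The test was limma (version 3.58.1, in R 4.3.3) with an intensity trend and without the robust option, on 9 arrays per tissue with group means for sham, 24 h and 48 h, two-sided, with Benjamini-Hochberg adjusted p-values under 0.05 called. Every adjusted p-value of a gene is from limma. The difference between the responses of kidney and liver was tested as a contrast in a fit of all 18 arrays. A group was taken as at the floor when all 3 arrays lay less than 1 above the lowest value, and a fold against such a group is a lower bound. Some sets give 1 identical value, to the last deposited digit, in several of the 18 arrays. A fold against a group with such a reading, or a value less than 1 above the lowest, in at least 1 array is also given as a lower bound, a rule added after the values were seen.

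The 35 gene lists hold 588 entries, of which 529 matched a named gene. They were tested with camera of limma with a preset correlation between genes of 0.01, adjusted over the 35 lists within a comparison, and again with an estimated correlation and with fry. For each list, genes were also counted with p-values adjusted over the list alone. Overlaps of called genes were set against the number for independent lists, with Fisher's exact test between the tissues. Between the times in a tissue, 50 data sets were simulated in which unchanged groups share simulated sham arrays. The rank product test, which the design text names, was run on the 9 pairwise ratios with 100 permutations.

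Genes were named by a rule: for each comparison with sham, the 6 largest rises and 6 largest falls among called genes whose treated arrays all lay beyond all sham arrays (unnamed clones and predicted genes skipped), up to 3 called members with the smallest p of each shifted list, and 16 genes of a panel. For other comparisons the 5 largest changes in each direction were named. Groups, gene lists, tests, the naming rule and the alternatives were fixed before the data were examined, except a filter at a value of 5 in at least 3 arrays, the list tests between 48 h and 24 h and between the tissues, and a restriction of the comparison of tissues to genes more than 1 above the floor in at least 3 arrays of each, which were added afterwards. The alternatives were no filter and a filter at percentile 60, all probe sets or their mean per gene, quantile normalization, median centring, no trend, the robust option, array weights, the array letter as a block, all 18 arrays or only the 6 arrays compared, and leaving out each array in turn.

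The methods were tested on simulated data made from the real arrays. Among 12071 liver genes, limma called 9%, 23.9% and 80.3% of genes changed by 0.5, 1 and 2 (log2) and 3 unchanged genes. Among 12003 kidney genes it called 22.4%, 67.2% and 89.4% and 12 unchanged genes. Camera called a list raised by 1 in 20 of 20 data sets in both tissues, and any list in 2 (liver) and 0 (kidney) of 20 data sets with no change. Genes were drawn independently there, so these runs cannot show how often camera calls a list when genes are correlated. The rank product test called 49 unchanged genes in each tissue.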

Results

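The series addressed kidney dysfunction during massive liver necrosis in the mouse. Male C57BL6 mice, a standard inbred strain, received an intraperitoneal injection of D-galactosamine (GalN), an amino sugar that injures hepatocytes selectively and depletes their uridine nucleotides, at 4.5 g per kg, or saline. Liver and kidney were taken 24 h after saline (sham), 24 h after GalN and 48 h after GalN, with 3 mice in each treatment group. RNA from each organ was hybridised to 1 Affymetrix mouse genome array per sample, which gave 18 arrays in 6 groups of 3. There was no sham group at 48 h, so the comparison of 48 h livers or kidneys with sham also compares different times after injection.

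Values are log2 gcRMA expression values, and means are given ± SD with n = 3. The medians of the 18 arrays lay between 2.36 and 2.43, close to the lowest value of 2.21, and 46.8% to 48.8% of the values of an array lay within 0.1 of that floor. The 75th percentiles ran from 6.43 to 7.05. Readings of a probe set that recur exactly in another array are taken as background: 89.5% of readings up to 3 recur, and 0.58% of those above 10. Folds against a group with such a reading, or with an array less than 1 above the floor, are lower bounds. Identical background readings also narrow the spread of a group. The limma p-values of such genes can therefore rest on too small a spread between animals. Arrays of 1 group correlated across probe sets with r between 0.983 and 0.998. Arrays have no read depth, and the 3 arrays per group limit the precision of every comparison.

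At 24 h after GalN, liver differed from sham liver in genes of several pathways. Cdkn1a, an inhibitor of cyclin-dependent kinases, rose at least 143-fold, from 6.25 ± 0.12 to 13.40 ± 0.033 (adjusted p = 7.74e-04). Cbr3, a carbonyl reductase, rose at least 144-fold from 3.36 ± 0.70 to 10.53 ± 0.32 (adjusted p = 4.73e-04). Tnfrsf12a, the receptor of the cytokine TWEAK, rose 45.5-fold to 10.66 ± 0.64 (adjusted p = 1.09e-04). Cyp8b1, the sterol 12-alpha-hydroxylase of bile acid synthesis, was at least 479-fold lower, at 4.24 ± 1.04 against 13.14 ± 0.17 in sham (adjusted p = 1.44e-04). G6pc, the catalytic subunit of glucose-6-phosphatase, was at least 114-fold lower, at 4.94 ± 2.63 against 11.77 ± 0.56 (adjusted p = 0.00497). Of the enzymes of steroid metabolism, Cyp17a1 was at least 101-fold and Hsd3b5 116-fold lower, and Upp2, a uridine phosphorylase, was 81.8-fold lower.

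Of 12071 genes tested in liver with limma, 3966 differed between 24 h and sham, 2161 higher and 1805 lower. Of these, 2718 differed at least 2-fold. The rank product test, which the series' design text names, called 597 genes, 570 of which limma also called in the same direction. Other genes with large rises were Epm2aip1 (68.1-fold) and Tubb6, a beta tubulin (at least 53.4-fold). Ddias, a DNA damage response gene, was at the floor in all 3 sham livers and reached 8.26 ± 0.80, at least 65.9-fold higher (adjusted p = 1.09e-04). It read 2.213 in every sham and 48 h liver. Those livers add no spread to its test, so its p can be too small. The transcript Hectd2os was at least 229-fold lower (adjusted p = 0.00325). Leaving out 1 array at a time gave counts from 2834 (without sham B) to 4652 (without 48 h C), and 46 of the 47 named calls held in every such fit that tested them. The exception was Cdh5, an endothelial cadherin (at least 2.42-fold higher), whose call was lost without sham A, B or C. Ddias passed the filter in liver only through its 24 h arrays, so it was not tested without 24 h A, B or C.

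Of the 35 gene lists, 13 shifted in liver at 24 h with camera, 7 up and 6 down. No list call against sham in either tissue remained with an estimated correlation between genes in place of the preset one, and that p is given beside each list. Over the alternatives of these 13 lists the adjusted p ran from 3.43e-12 to 0.357, the highest being that with an estimated correlation. Cholesterol synthesis fell most: 13 of its 16 measured members fell, 0 rose and 3 were not called, with 14 lower when adjusted over the list alone (median log2 change -2.83, adjusted p = 4.94e-09, adjusted p = 0.289 with an estimated correlation). Dhcr7, which makes cholesterol from its last precursor, went from 12.33 ± 0.32 to 7.91 ± 0.23 (adjusted p = 1.09e-04), and Insig1, a regulator of sterol synthesis, and Sc5d fell by 3.17 and 2.67 on the log2 scale. Of 15 genes of the urea cycle and amino acid breakdown, 11 fell and 4 were not called, with 13 lower when adjusted over the list alone (median -1.12, adjusted p = 1.20e-06, adjusted p = 0.117 with an estimated correlation). Among them Kynu, an enzyme of tryptophan breakdown, fell by 4.62, Hal, which degrades histidine, by 3.31, and Got1, an aspartate aminotransferase, by 2.52. Of 10 genes of gluconeogenesis and glycogen metabolism, 8 fell, and all 10 were lower when adjusted over the list alone (median -1.53, adjusted p = 7.94e-05, adjusted p = 0.117 with an estimated correlation). Gys2, liver glycogen synthase, fell by 2.78, and Slc2a2, the hepatocyte glucose transporter, fell by 1.87.

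Of 16 genes of bile acid synthesis and transport, 8 fell, 1 rose and 7 were not called, with 9 lower and 1 higher when adjusted over the list alone (median -1.08, adjusted p = 0.0082, adjusted p = 0.289 with an estimated correlation). The basolateral uptake carriers Slco1b2 and Slc10a1 fell by 2.28 and 1.12. Of 22 acute phase genes, 10 fell, 1 rose and 11 were not called, with 13 lower and 1 higher when adjusted over the list alone (median -0.63, adjusted p = 1.97e-04, adjusted p = 0.357 with an estimated correlation). Crp and Apcs, both pentraxins, fell by 2.62 and 2.42, and Fgg, the fibrinogen gamma chain, by 0.46. The sham livers themselves were unequal in this list: Saa1, serum amyloid A, stood at 12.54, 15.30 and 15.47 in sham A, B and C and Lcn2 at 11.46, 13.45 and 14.13. The differences of Saa1 (-3.27, adjusted p = 0.0927) and Lcn2 (-2.41, adjusted p = 0.103) from sham were not called at 24 h. Of 12 circadian clock genes, 4 fell and 8 were not called, with 4 lower when adjusted over the list alone (median -0.57, adjusted p = 0.0171, adjusted p = 0.357 with an estimated correlation). They included Dbp (fell by 3.24), Bhlhe40 (fell by 1.45) and Tef (fell by 0.92), transcription factors of the clock and its output.

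Among the lists that rose at 24 h, 14 of 16 genes of ribosome biogenesis rose and 2 were not called, with 15 higher when adjusted over the list alone (median 1.96, adjusted p = 4.34e-08, adjusted p = 0.274 with an estimated correlation). Nop56 and Nop2, nucleolar proteins of ribosomal RNA processing, rose 5.53-fold and 5.08-fold, and Dkc1, a pseudouridine synthase, 3.59-fold. Of 13 p53 target genes, 10 rose and 3 were not called, with 10 higher when adjusted over the list alone (median 2.78, adjusted p = 1.75e-06, adjusted p = 0.145 with an estimated correlation). Besides Cdkn1a, they included Phlda3 (at least 39.3-fold), Aen (at least 26.6-fold) and Zmat3 (15.8-fold). Of 13 antioxidant genes of the NRF2 set, 6 rose and 7 were not called, with 6 higher when adjusted over the list alone (median 0.48, adjusted p = 0.0031, adjusted p = 0.357 with an estimated correlation). Srxn1, sulfiredoxin, rose 29-fold, Hmox1, haem oxygenase, 12.7-fold and Txnrd1, thioredoxin reductase, 4.4-fold. Of 12 death receptor and apoptosis genes, 5 rose, 1 fell and 6 were not called, with 7 higher and 1 lower when adjusted over the list alone (median 1.02, adjusted p = 0.0171, adjusted p = 0.357 with an estimated correlation). Besides Tnfrsf12a these included Bcl2l1 (3.34-fold) and Mcl1 (2.16-fold), both of which encode proteins that oppose apoptosis.

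Endothelial and macrophage markers were also higher in the 24 h livers. Of 13 endothelial markers, 6 rose and 7 were not called, with 8 higher when adjusted over the list alone (median 1.02, adjusted p = 0.00393, adjusted p = 0.357 with an estimated correlation), including Lyve1, a hyaluronan receptor (16.3-fold), and Esam, an adhesion molecule (2.64-fold). Of 15 macrophage markers, 8 rose and 7 were not called, with 9 higher when adjusted over the list alone (median 0.88, adjusted p = 0.00633, adjusted p = 0.357 with an estimated correlation), including Cd68 (at least 8.55-fold), the complement gene C1qb (2.84-fold) and Cd5l (2.44-fold). Lists of other liver cells did not shift with camera. Of 14 myofibroblast and matrix genes, 4 rose and 1 fell (camera adjusted p = 0.222). Of neutrophil, lymphocyte and cholangiocyte or progenitor markers, 0 of 5, 0 of 3 and 0 of 10 were called (camera adjusted p = 0.82, 0.764 and 0.785), though fry called the lymphocyte list (adjusted p = 0.00514). Fry alone also called the erythroid, proximal tubule and distal nephron lists in liver (adjusted p = 0.0418, 0.00385 and 0.0229). Of 16 genes listed as markers of kidney tubular injury, 8 rose and 8 were not called in liver, with 8 higher when adjusted over the list alone (median 1.02, adjusted p = 0.0127, adjusted p = 0.357 with an estimated correlation). Cdkn1a and Tnfrsf12a are among them, as is Lgals3, galectin-3, a lectin also made by macrophages (13.9-fold). The list of hepatocyte plasma proteins did not shift, with 0 of 18 members called (median -0.08, camera adjusted p = 0.26, fry adjusted p = 0.169). Alb, albumin, was 16.46 ± 0.10 against 16.34 ± 0.15 (adjusted p = 0.374). Cyp2e1 was 15.64 ± 0.084 against 15.69 ± 0.052 (adjusted p = 0.64), Cyp7a1 9.24 ± 0.70 against 10.11 ± 0.64 (adjusted p = 0.224) and Afp, alpha-fetoprotein, 7.55 ± 0.53 against 6.98 ± 1.22 (adjusted p = 0.556). Rplp0, a ribosomal protein gene used as a reference in the study, rose by 0.39 (adjusted p = 0.009), while Gapdh, the study's other reference gene, has no set named for it alone. Tnf, Havcr1, Umod, Slc34a1 and Mki67 were at the floor in both groups.

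**Figure D1:**
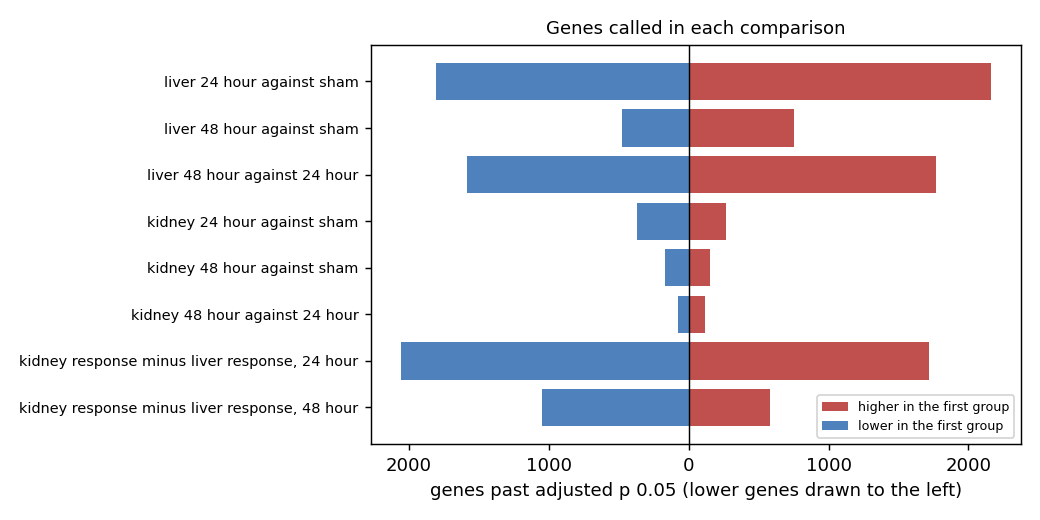
Number of genes past an adjusted p of 0.05 with limma in each comparison (horizontal axis, genes, starting at 0 in the middle), with genes higher in the first group named drawn to the right and lower genes to the left. Liver at 24 h has the most calls against sham (2161 higher and 1805 lower) and kidney at 48 h the fewest (155 higher and 168 lower). Without kidney sham B the order of the kidney comparisons turns, with 15 genes at 24 h and 42 at 48 h.

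At 48 h, fewer genes differed from sham in liver, and they included Afp and genes of fat metabolism. Afp, a fetal hepatocyte protein, rose 16.8-fold, from 6.98 ± 1.22 to 11.05 ± 0.67 (adjusted p = 0.0131). Cidec, a lipid droplet protein, rose at least 30.5-fold from 4.22 ± 0.14 to 9.15 ± 0.38 (adjusted p = 0.00148), Acot1, an acyl-CoA thioesterase, 15.7-fold (adjusted p = 0.00148) and Pdk4, which restrains glucose oxidation, at least 12.1-fold (adjusted p = 0.00661). Slco1a1, an organic anion carrier of the hepatocyte membrane, was 18.8-fold lower, at 7.52 ± 0.44 against 11.75 ± 0.22 (adjusted p = 0.00148). Scd1, the stearoyl-CoA desaturase of fat synthesis, was 14.3-fold lower (adjusted p = 0.00697). Bhlhb9 rose at least 36.5-fold and Cbr3 at least 21-fold. The set named for Rps25, a ribosomal protein gene, rose at least 30.8-fold. It read only 2.97 to 3.67 in every sham liver and kidney array, where Rplp0, another ribosomal protein gene, read 14.7 or more. The set may therefore not report the main Rps25 transcript, and a rise of that transcript is not shown. Mtnr1a, a melatonin receptor at the floor in sham, was at least 25.4-fold higher, while Cyp2u1 was at least 15-fold and Hsd3b5 14.9-fold lower.

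Of 12071 genes, 1228 differed between 48 h and sham with limma, 753 higher and 475 lower, and 669 at least 2-fold. By rank product 285 were called, of which 205 were shared with limma in the same direction. The count depended on single arrays: it was 448 without sham B, 595 without sham C, 604 without 48 h A and 804 without sham A. It was higher with array weights (4728) and with all 18 arrays in 1 fit (2492). Of 54 named calls, 39 held whichever array was left out, and 13 were lost without sham B, 12 without 48 h A, 11 without sham C, 8 without sham A, 8 without 48 h B, 3 without 24 h B and 2 each without 24 h A, 24 h C and 48 h C. The array 48 h C stood apart from A and B of its group. Its gap between the 3' and 5' control sets of actin was 2.56, against 1.48 to 1.86 in the sham livers, and its residual SD was 0.487.

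Of the 35 lists, 15 shifted in liver at 48 h with camera, 6 up and 9 down, and over their alternatives the adjusted p ran from 7.3e-16 to 0.611. Cholesterol synthesis was again low, with 13 of 16 members falling, 3 not called and 13 lower when adjusted over the list alone (median -1.92, adjusted p = 7.12e-12, adjusted p = 0.202 with an estimated correlation). Nsdhl fell by 3.07, Cyp51 by 2.69 and Dhcr7 by 2.13. Plasma protein genes of hepatocytes fell at this time: 12 of 18 fell and 6 were not called, with 15 lower when adjusted over the list alone (median -0.40, adjusted p = 1.80e-11, adjusted p = 0.131 with an estimated correlation). The coagulation genes F9, F2 and Serpinc1 fell by 1.34, 0.54 and 0.52, and Alb was 16.21 ± 0.082 against 16.34 ± 0.15 (adjusted p = 0.455). Of 22 acute phase genes, 6 fell and 16 were not called, with 13 lower and 1 higher when adjusted over the list alone (median -0.51, adjusted p = 9.43e-06, adjusted p = 0.351 with an estimated correlation), among them Itih4 (fell by 1.16), Orm1 (fell by 1.12) and the haem carrier Hpx (fell by 0.47). Of 16 drug-metabolising enzymes, 4 fell and 12 were not called, with 9 lower when adjusted over the list alone (median -0.47, adjusted p = 0.00125, adjusted p = 0.202 with an estimated correlation), among them Cyp1a2 (fell by 1.38) and Cyp2c50 (fell by 0.81).

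Of 16 bile acid genes, 7 fell, 2 rose and 7 were not called, with 8 lower and 2 higher when adjusted over the list alone (median -0.53, adjusted p = 0.00518, adjusted p = 0.202 with an estimated correlation), and Slc10a1 fell by 0.84. Of 15 genes of the urea cycle and amino acid breakdown, 3 fell and 12 were not called, with 4 lower when adjusted over the list alone (median -0.61, adjusted p = 1.16e-04, adjusted p = 0.186 with an estimated correlation), among them Hpd, of tyrosine breakdown (fell by 0.68). Of 10 genes of gluconeogenesis and glycogen metabolism, 3 fell and 7 were not called, with 6 lower when adjusted over the list alone (median -0.69, adjusted p = 5.12e-04, adjusted p = 0.131 with an estimated correlation), among them Slc2a2 (fell by 1.08) and Fbp1 (fell by 0.95). Of 12 circadian genes, 3 fell, 1 rose and 8 were not called, with 5 lower and 1 higher when adjusted over the list alone (median -0.67, adjusted p = 0.00566, adjusted p = 0.351 with an estimated correlation), with Dbp falling by 1.85 and Bhlhe40 by 1.79. Of 19 genes of oxidative phosphorylation, 1 fell, Sdha, by 0.88, with 3 lower when adjusted over the list alone (median -0.13, adjusted p = 0.00555, adjusted p = 0.611 with an estimated correlation). That call was also lost with fry, without 48 h A (adjusted p = 0.0717) and without 48 h B (adjusted p = 0.0991).

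Fatty acid oxidation rose at 48 h, with 4 of 17 members rising, 13 not called and 5 higher when adjusted over the list alone (median 0.35, adjusted p = 0.00518, adjusted p = 0.451 with an estimated correlation), and Acadm, an acyl-CoA dehydrogenase, rose 1.76-fold. Of 13 p53 targets, 5 rose and 8 were not called, with 6 higher when adjusted over the list alone (median 0.81, adjusted p = 5.12e-04, adjusted p = 0.202 with an estimated correlation), among them Aen (at least 3.71-fold) and Perp (2.43-fold). Of 16 ribosome biogenesis genes, 3 rose and 13 were not called, with 3 higher when adjusted over the list alone (median 0.61, adjusted p = 0.00125, adjusted p = 0.351 with an estimated correlation), among them Npm1 (2.07-fold) and Nop56 (2.04-fold). Of 17 cell cycle genes, 1 rose and 16 were not called, with 1 higher when adjusted over the list alone (median 0.61, adjusted p = 0.00598, adjusted p = 0.351 with an estimated correlation). The gene was Cdk1, the mitotic kinase, which rose 2.64-fold to 5.27 ± 0.15 (adjusted p = 0.00148). Of 15 macrophage markers, 3 rose and 12 were not called, with 3 higher when adjusted over the list alone (median 0.63, adjusted p = 0.00134, adjusted p = 0.351 with an estimated correlation), and C1qb rose 2.18-fold. Cdkn1a rose at least 12.3-fold over sham (adjusted p = 0.0298), but with 10.86 and 10.92 in 48 h A and B and 7.82 in 48 h C.

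Of 16 kidney injury markers, 5 rose in liver at 48 h and 11 were not called, with 6 higher when adjusted over the list alone (median 0.71, adjusted p = 0.0396, adjusted p = 0.421 with an estimated correlation). Lgals3 rose 18.2-fold and Tnfrsf12a 6.18-fold. This call was also lost with the array letter as a block, and without sham B (adjusted p = 0.109), sham C (0.0587), 24 h A (0.0555), 24 h B (0.0527) or 48 h B (0.11). Cyp2e1 was 15.43 ± 0.097 against 15.69 ± 0.052 (adjusted p = 0.069), Cyp7a1 9.77 ± 0.62 (adjusted p = 0.727), Hmox1 8.85 ± 0.56 against 7.69 ± 0.45 (adjusted p = 0.0773), Mki67 3.92 ± 1.42 against 2.55 ± 0.009 (adjusted p = 0.221), Saa1 10.98 ± 0.86 (adjusted p = 0.146) and Lcn2 10.36 ± 0.71 (adjusted p = 0.145), none of them called. Rplp0 rose by 0.38 (adjusted p = 0.0282).

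Between 24 h and 48 h in liver, Cyp8b1 rose at least 158-fold, from 4.24 ± 1.04 to 11.54 ± 0.89 (adjusted p = 4.95e-04), and G6pc at least 146-fold, from 4.94 ± 2.63 to 12.13 ± 0.70 (adjusted p = 0.00481). Hectd2os rose at least 52.5-fold and Fam47e at least 49.9-fold, and Lrit1, at the floor at 24 h, rose at least 42.6-fold. Among genes that fell, Epm2aip1 was 32-fold lower at 48 h, 9230114K14Rik 25.4-fold lower and Plk2, a polo-like kinase induced by p53, 20.8-fold lower. The array 48 h C adds to the first 2 of these folds. Epm2aip1 stood at 6.48, 7.04 and 4.25 in 48 h A, B and C, and 9230114K14Rik at 6.42, 6.42 and 3.76. That array also adds to the rise of Hectd2os, which stood at 9.121, 7.705 and 12.375 in 48 h A, B and C. The 52.5-fold is therefore a lower bound only for the mean that includes 48 h C. Ddias and Eda2r, a p53-induced receptor, were at the floor at 48 h, at least 65.9-fold and at least 23.4-fold lower. In all, 3355 of 12071 genes differed with limma (1768 higher and 1587 lower at 48 h), 2157 of them at least 2-fold. The rank product test called 477, with 446 shared.

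Of the 35 lists, 8 shifted between the times in liver. Lower at 48 h were ribosome biogenesis (10 of 16 fell, 13 when adjusted over the list alone, median -1.42, adjusted p = 1.53e-05, adjusted p = 0.487 with an estimated correlation) and p53 targets (9 of 13 fell and 1 rose, 10 and 1 when adjusted over the list alone, median -2.04, adjusted p = 1.38e-04, adjusted p = 0.487 with an estimated correlation). Plasma protein genes were lower too (10 of 18 fell, 12 when adjusted over the list alone, median -0.32, adjusted p = 1.38e-04, adjusted p = 0.487 with an estimated correlation), as were NRF2 genes (5 of 13 fell, 6 when adjusted over the list alone, median -0.45, adjusted p = 0.0184, adjusted p = 0.871 with an estimated correlation). The endothelial list was lower with 0 of 13 members called by limma (median -0.76, adjusted p = 0.0218, adjusted p = 0.871 with an estimated correlation). Higher at 48 h were fatty acid oxidation (8 of 17 rose, 10 when adjusted over the list alone, median 0.70, adjusted p = 1.38e-04, adjusted p = 0.65 with an estimated correlation), the urea cycle and amino acid list (7 of 15 rose and 2 fell, 9 and 2 when adjusted over the list alone, median 0.56, adjusted p = 0.0115, adjusted p = 0.487 with an estimated correlation) and cholesterol synthesis (7 of 16 rose, 7 higher and 1 lower when adjusted over the list alone, median 0.85, adjusted p = 0.0115, adjusted p = 0.871 with an estimated correlation).

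**Figure D2:**
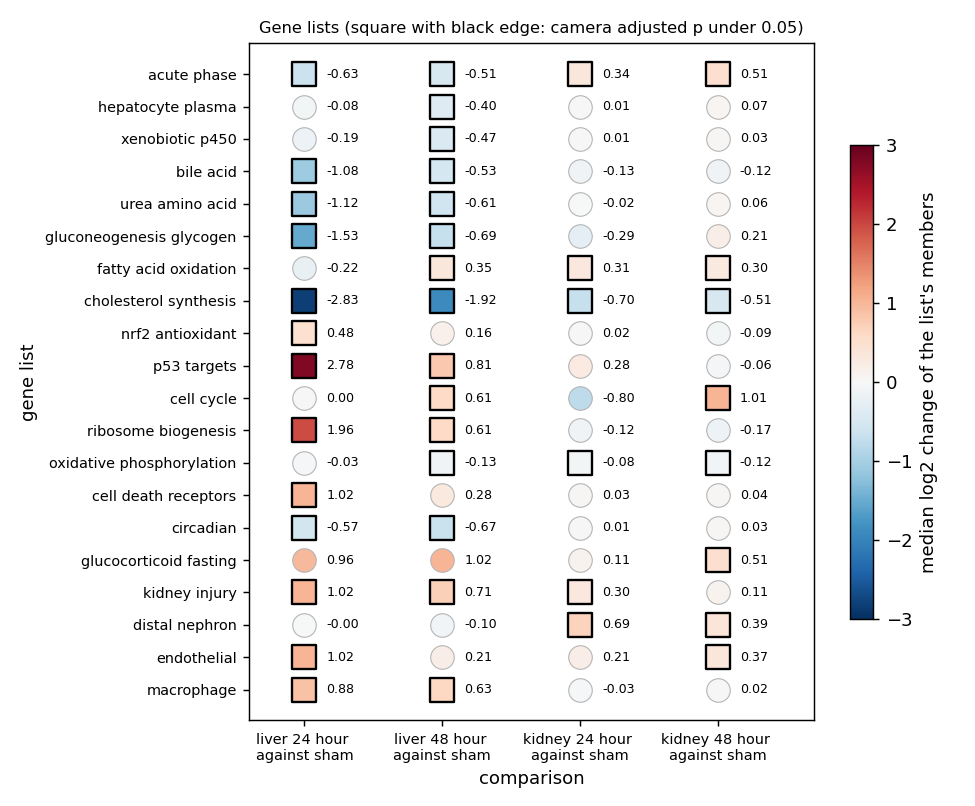
Median log2 change of each list's measured members (colour and printed value) against sham in liver and kidney at 24 h and 48 h, for the lists with a camera adjusted p under 0.05 in at least 1 of these comparisons; squares with a black edge pass it and circles do not. Cholesterol synthesis is lower in all of them, from -2.83 in liver at 24 h to -0.51 in kidney at 48 h.

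In kidney at 24 h, the genes higher than in sham kidney included Lcn2, Serpina1b, Cyp4a14 and the subunits of the epithelial sodium channel. Lcn2, the iron-binding lipocalin NGAL, rose at least 27.1-fold, from 3.93 ± 1.06 to 8.69 ± 0.75 (adjusted p = 0.0225). Serpina1b, an alpha-1-antitrypsin gene, rose at least 18.6-fold from 4.07 ± 0.033 to 8.29 ± 0.29 (adjusted p = 1.11e-04). Cyp4a14, a fatty acid hydroxylase induced through PPAR alpha, rose 12.3-fold to 11.83 ± 0.68 (adjusted p = 0.0254). Kcnj10, a basolateral potassium channel of the distal tubule, rose 7.56-fold (adjusted p = 0.0167). Cables1 rose at least 4.61-fold and Slc25a25, a mitochondrial carrier, 4.37-fold. Idi1, an enzyme of the mevalonate pathway, was 6.25-fold lower (adjusted p = 0.0198). Slc51a, a subunit of the basolateral bile acid and steroid carrier, was 5.76-fold lower, at 8.10 ± 0.99 against 10.62 ± 0.20 (adjusted p = 0.0308). Ugt2b5, a glucuronosyltransferase, was at the floor at 24 h, at least 6.68-fold lower. Hepacam2 was at least 4.73-fold lower, and Zc3h12c and Ftcd were 4.19-fold and 3.92-fold lower.

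Of 12003 genes tested in kidney, 637 differed between 24 h and sham with limma, 265 higher and 372 lower, and 113 at least 2-fold. The share of higher genes was 41.6%, and 51.1% after quantile normalization, so the side with more genes depends on the scaling. By rank product 180 were called, of which 73 were shared in the same direction. The count was 15 without sham B, 109 without sham A, 115 without 24 h B, 198 without sham C and 263 without 48 h B. Serpina1b, Fgg and Tnfrsf12a were the 3 of 25 named calls that held whichever array was left out. Sham readings of Serpina1b and Tnfrsf12a recur in other arrays, so their spread may be too small in these fits. Of those 25, 22 were lost without sham B, 18 without 24 h B, 17 without sham A, 8 without sham C, 8 without 48 h B, 7 without 24 h A, 7 without 24 h C, 3 without 48 h C and 1 without 48 h A.

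Of the 35 lists, 6 shifted in kidney at 24 h, 4 up and 2 down, and over their alternatives the adjusted p ran from 8.95e-09 to 0.912. Of 16 genes of cholesterol synthesis, 4 fell and 12 were not called, with 10 lower when adjusted over the list alone (median -0.70, adjusted p = 3.74e-06, adjusted p = 0.572 with an estimated correlation). Besides Idi1 these included Nsdhl (fell by 0.96) and Sc5d (fell by 0.83). Of 17 genes of fatty acid oxidation, 2 rose, Cyp4a14 and Hadha (1.46-fold), and 15 were not called, with 6 higher when adjusted over the list alone (median 0.31, adjusted p = 0.00561, adjusted p = 0.572 with an estimated correlation). Of 17 markers of the distal nephron, 3 rose and 14 were not called, with 4 higher and 1 lower when adjusted over the list alone (median 0.69, adjusted p = 0.00943, adjusted p = 0.572 with an estimated correlation). The 3 were the subunits of the epithelial sodium channel: Scnn1b rose 2.79-fold to 7.90 ± 0.29, Scnn1a 2.07-fold to 9.67 ± 0.22 and Scnn1g 1.84-fold to 8.73 ± 0.11. Fry did not call the fatty acid and distal nephron lists (adjusted p = 0.081 and 0.0664).

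Of 18 acute phase genes, 3 rose and 15 were not called, with 4 higher when adjusted over the list alone (median 0.34, adjusted p = 0.0307, adjusted p = 0.572 with an estimated correlation). They were Lcn2, Fgg (2.86-fold, to 9.75 ± 0.12, adjusted p = 0.0062) and Cd14, a receptor for bacterial lipopolysaccharide (at least 1.53-fold). The call was lost after quantile normalization, without 24 h B (adjusted p = 0.146) and without sham A (adjusted p = 0.0684). Of 16 kidney injury markers, 3 rose and 13 were not called, with 5 higher when adjusted over the list alone (median 0.31, adjusted p = 0.0167, adjusted p = 0.572 with an estimated correlation). They were Lcn2, Tnfrsf12a (at least 2.6-fold, adjusted p = 0.0101) and Lgals3 (2.43-fold, adjusted p = 0.0192), and the call was lost without sham C (adjusted p = 0.0705). Of 19 genes of oxidative phosphorylation, 4 fell and 15 were not called, with 4 lower when adjusted over the list alone (median -0.08, adjusted p = 0.0307, adjusted p = 0.77 with an estimated correlation). Uqcrc2, Ndufb5 and Cox5a fell by 0.43, 0.36 and 0.24, and the call was lost with fry, after quantile normalization, with a filter at a value of 5, and without sham A (adjusted p = 0.0684), 24 h B (0.0885) or 24 h C (0.162).

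The hybridisation control bioB, added to each sample, was 9.47 ± 0.038 in sham kidneys and 8.95 ± 0.11 and 8.92 ± 0.16 at 24 h and 48 h. All sham kidneys (lowest 9.43) lay above all treated kidneys (highest 9.10). This technical difference runs along with treatment in kidney. The same holds in liver at 24 h, where all sham livers (lowest 10.08) lay above all livers of 24 h (highest 9.89). At 48 h the livers overlapped with sham, with 48 h C at 10.135. The effect of these bioB differences on the calls was not tested in either tissue. The gap between the 3' and 5' control sets of actin was 1.85 ± 0.15, 1.54 ± 0.087 and 1.69 ± 0.059, and lower in all 3 kidneys of 24 h than in all sham kidneys. Hepatocyte plasma protein genes did not shift as a list in kidney at 24 h, with 0 of 16 called (median 0.01, camera adjusted p = 0.846, fry adjusted p = 0.741). The list of 21 proximal tubule genes did not shift, with 1 gene higher, 1 lower and 19 not called (median -0.09, adjusted p = 0.541). Slc34a1, the proximal phosphate carrier, was 14.57 ± 0.047 against 14.65 ± 0.19 (adjusted p = 0.596), and Umod, uromodulin of the thick ascending limb, 15.75 ± 0.11 against 15.95 ± 0.020 (adjusted p = 0.084). Havcr1, which encodes the injury marker KIM-1, was at the floor in both groups, as were Tnf and Saa1. Alb was 8.10 ± 0.29 against 8.24 ± 0.18 (adjusted p = 0.733), Cdkn1a 7.12 ± 0.29 against 6.40 ± 0.047 (adjusted p = 0.0669), Hmox1 8.45 ± 0.33 against 9.19 ± 0.27 (adjusted p = 0.263) and Rplp0 15.02 ± 0.007 against 14.85 ± 0.13 (adjusted p = 0.168). Cyp2e1 was 15.16 in both groups (adjusted p = 1), and Afp, Cyp7a1 and Mki67 were not called either (adjusted p = 0.968, 0.959 and 0.509).

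**Figure D3:**
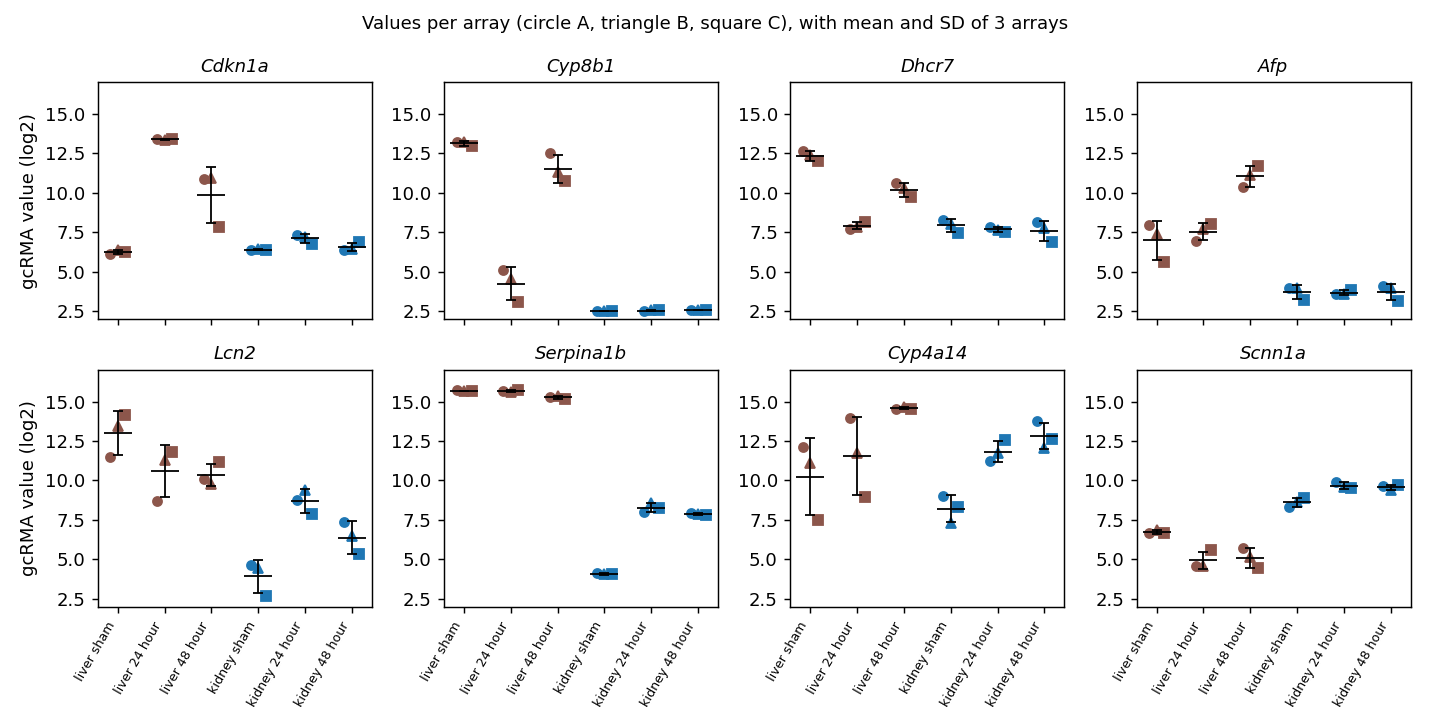
gcRMA values (vertical axis, log2) of 8 genes in the 6 groups of liver (brown) and kidney (blue) arrays, with circle, triangle and square for arrays A, B and C, a long line for the mean and bars for the SD of 3 arrays. Cdkn1a is at 13.40 in the 24 h livers against 6.25 in sham, and Serpina1b at 8.29 in the 24 h kidneys against 4.07 in sham.

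At 48 h, Cyp4a14 and Serpina1b had the largest folds among the named kidney genes. Cyp4a14 rose 24.4-fold, from 8.21 ± 0.86 to 12.82 ± 0.85 (adjusted p = 0.0234), and Serpina1b at least 13.9-fold, to 7.87 ± 0.063 (adjusted p = 2.34e-04). Rsph9 rose 4.45-fold, Kynu at least 4.17-fold, Ackr4, a scavenging chemokine receptor, 3.8-fold and Tmem37 3.76-fold. Slc51a was 7-fold lower, at 7.82 ± 0.28 against 10.62 ± 0.20 (adjusted p = 0.0321). Ccl28, a mucosal chemokine, 4.89-fold lower and Bcat1, a branched-chain aminotransferase, 4.59-fold lower. Idi1 was 4.02-fold, Serpinc1, antithrombin, 3.4-fold and Vill 3.29-fold lower. Lcn2 was 6.38 ± 1.04 against 3.93 ± 1.06 and was not called (adjusted p = 0.122).

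Of 12003 genes, 323 differed between 48 h and sham with limma, 155 higher and 168 lower, and 73 at least 2-fold. The share of higher genes was 48%, 54.4% after quantile normalization and 43.4% after median centring. By rank product 224 were called, of which 68 were shared in the same direction. The count was 29 without sham A, 31 without 48 h B, 42 without sham B, 45 without 48 h C, 168 without 48 h A and 181 without sham C. It was higher with array weights (1245) and with a filter at a value of 5 (512). Of 22 named calls, Serpina1b (with recurring sham readings), Ackr4 and Cycs were the 3 that held whichever array was left out. The others were lost in different fits, 19 without 48 h B, 19 without sham A, 18 without 48 h C, 16 without sham B, 11 without 48 h A, 9 without 24 h C, 8 without sham C, 5 without 24 h B and 1 without 24 h A.

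Of the 35 lists, 8 shifted in kidney at 48 h with camera, 6 up and 2 down, fry called 0 of the 35, and over the alternatives of the 8 the adjusted p ran from 1.16e-06 to 0.807. Of 17 genes of fatty acid oxidation, 3 rose and 14 were not called, with 5 higher when adjusted over the list alone (median 0.30, adjusted p = 5.91e-05, adjusted p = 0.64 with an estimated correlation). Besides Cyp4a14 they were the thiolases Acaa1b (2.22-fold) and Acaa2 (1.53-fold). Of 16 genes of cholesterol synthesis, 3 fell and 13 were not called, with 4 lower when adjusted over the list alone (median -0.51, adjusted p = 1.11e-04, adjusted p = 0.64 with an estimated correlation), and Mvd and Nsdhl fell by 0.78 and 0.71. Of 17 distal nephron markers, 2 rose and 15 were not called, with 3 higher when adjusted over the list alone (median 0.39, adjusted p = 9.47e-04, adjusted p = 0.64 with an estimated correlation). They were Scnn1a (1.95-fold) and Egf, made in the distal tubule (1.58-fold). Of 19 genes of oxidative phosphorylation, 1 fell, Cycs, cytochrome c, by 0.44, with 4 lower when adjusted over the list alone (median -0.12, adjusted p = 0.00121, adjusted p = 0.643 with an estimated correlation).

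Of 18 acute phase genes, 2 rose at 48 h and 16 were not called, with 2 higher when adjusted over the list alone (median 0.51, adjusted p = 0.0159, adjusted p = 0.64 with an estimated correlation). They were Fgg (1.7-fold) and Fgb, at the floor in sham (at least 1.68-fold), and the call was lost without 48 h C (adjusted p = 0.057). Of 16 genes of the glucocorticoid and fasting response, 1 rose, Igfbp1 (3.01-fold), with 1 higher when adjusted over the list alone (median 0.51, adjusted p = 0.0159, adjusted p = 0.807 with an estimated correlation). That call was lost without 48 h C (adjusted p = 0.333), sham A (0.175) or sham B (0.0941). The cell cycle list was higher with 0 of 19 members called (median 1.01, adjusted p = 0.0159, adjusted p = 0.807 with an estimated correlation), and the call was lost with a filter at a value of 5, without 48 h A (adjusted p = 0.401) and without sham C (adjusted p = 0.218). Array 48 h A stood apart in this list, with Mki67, a proliferation marker, at 7.73 against 3.79 and 2.93 in 48 h B and C. The sham kidneys were unequal too, with Mki67 at 3.53, 5.48 and 2.42 in sham A, B and C. The endothelial list was higher with 0 of 13 members called and 2 higher when adjusted over the list alone (median 0.37, adjusted p = 0.0446, adjusted p = 0.669 with an estimated correlation). It was lost without 48 h A (adjusted p = 0.0575), 48 h B (0.191), sham A (0.0504), sham B (0.106) or sham C (0.0648).

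The 21 proximal tubule genes did not shift at 48 h, with 3 higher, 2 lower and 16 not called (median 0.06, adjusted p = 0.56). Slc34a1 was 14.72 ± 0.015 (adjusted p = 0.75), Umod 15.93 ± 0.014 (adjusted p = 0.95), Alb 7.76 ± 0.30 (adjusted p = 0.258), Cdkn1a 6.57 ± 0.26 (adjusted p = 0.649), Hmox1 8.86 ± 0.69 (adjusted p = 0.683) with a difference of 0.15 from sham for Rplp0 (adjusted p = 0.273). Havcr1 was 3.04 ± 0.26 against a sham at the floor (adjusted p = 0.809), and Cyp2e1, Afp, Cyp7a1 and Mki67 were not called (adjusted p = 0.883, 1, 1 and 0.737). Tnf and Saa1 were at the floor.

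Between 24 h and 48 h in kidney, Syn3 rose 9.13-fold, from 5.03 ± 0.32 to 8.22 ± 0.36 (adjusted p = 0.0444), Igfbp1, an insulin-like growth factor binding protein, 6.47-fold (adjusted p = 0.0176), Clec2h 5.42-fold and 4931408D14Rik 4.57-fold. Nusap1, a mitotic spindle protein at the floor at 24 h, rose at least 17.4-fold, to 6.52 ± 1.21 (adjusted p = 0.0459). Mfsd2a, a lysophospholipid carrier, was 12-fold lower at 48 h, Slc25a25 9.07-fold and Bcat1 3.39-fold lower, and Bdnf and Asb11, at the floor at 48 h, were at least 3.72-fold and 3.37-fold lower. Of 12003 genes, 193 differed with limma, 115 higher and 78 lower, and the rank product test called 147, with 40 shared. The count was 1 without 48 h A, 15 without 48 h B, 21 without 48 h C, 26 without 24 h C, 53 without sham B, 76 without sham A and 111 without 24 h B. All 10 named calls were lost in at least 1 of these fits: 10 without 48 h A, 9 without 48 h B, 8 without 48 h C, 7 without 24 h C, 6 without 24 h B, 6 without sham B, 5 without sham A, 5 without 24 h A and 2 without sham C.

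Of the 35 lists, 3 shifted between the times in kidney with camera, and fry called 1 of the 35. The cell cycle list was higher at 48 h with 0 of 19 members called over all genes and 7 higher when adjusted over the list alone (median 1.75, adjusted p = 1.50e-05, adjusted p = 0.813 with an estimated correlation). Array 48 h A stood apart here, with Mki67 at 7.73 against 3.79 and 2.93 in 48 h B and C and Cdk1 at 9.46 against 6.29 and 5.71. Gluconeogenesis and glycogen metabolism was higher, with 2 of 10 rising and 4 when adjusted over the list alone (median 0.18, adjusted p = 0.025, adjusted p = 0.813 with an estimated correlation). Heat shock proteins were lower with 0 of 11 called and 1 when adjusted over the list alone (median -0.22, adjusted p = 0.025, adjusted p = 0.813 with an estimated correlation).

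The responses of the tissues were compared directly, as the kidney change minus the liver change, in 1 fit of all 18 arrays. At 24 h, Cyp8b1 (8.92, adjusted p = 4.94e-07), Hectd2os (7.84), Lcn2 (7.17, adjusted p = 6.73e-04), Cyp17a1 (6.74) and Hsd3b5 (6.72) were among the positive differences on the log2 scale, and Cdkn1a (-6.44, adjusted p = 5.79e-05), Cbr3 (-6.10), Ddias (-6.04), Epm2aip1 (-5.92) and Tubb6 (-5.86) among the negative ones. At 48 h they were Cyp17a1 (5.28), Lcn2 (5.11, adjusted p = 0.0156), Saa2, a serum amyloid A (5.02), Hsd3b5 (4.26) and Serpina1b (4.196, adjusted p = 2.17e-09), and Psat1, of serine synthesis (-5.30), Rps25 (-4.96), Mtnr1a (-4.67), Bhlhb9 (-4.60) and Acot9 (-4.13). In the kidneys compared, Cyp8b1, Hectd2os, Cyp17a1, Hsd3b5 and, at 48 h, Saa2 gave readings at or near background, where no fall can be measured, so their differences restate the liver changes. In at least 1 array each, sham readings of Lcn2 (kidney), Cdkn1a, Cbr3, Ddias, Tubb6, Rps25, Mtnr1a, Bhlhb9, Psat1 and Serpina1b also recur or lie at the floor, so neither the exact size nor the rank of their differences is known. The Rps25 set read 2.97 to 3.67 in every kidney array and may not report the main Rps25 transcript. Lcn2 was not called in liver at 24 h (adjusted p = 0.103) or 48 h (adjusted p = 0.145), nor in kidney at 48 h. Its sham livers were unequal (11.46, 13.45 and 14.13 in A, B and C), as were those of Saa2 (11.05, 15.82 and 15.94). Of 12467 genes, the responses differed for 3778 at 24 h (1721 with the more positive change in kidney and 2057 in liver) and for 1633 at 48 h (584 and 1049). All 10 named calls at 24 h held whichever array was left out, and 8 of 10 at 48 h. The calls of Cyp17a1 and Saa2 did not, and between 1 and 2 of the 10 were lost without liver sham A, B or C, liver 24 h B or C, liver 48 h A or B, or any kidney array except 24 h B. After quantile normalization the share of 48 h calls more positive in kidney was 46% in place of 35.8%, and array weights gave 4537 genes at 48 h. Of the called genes, 248 at 24 h and 133 at 48 h were at the floor in every kidney array. Among 10043 genes above the floor in at least 3 arrays of each tissue, the responses differed for 3526 and 1491.

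Among the 35 lists, 15 differed between the tissues at 24 h and 12 at 48 h, and 3 and 1 of them also with an estimated correlation. At 24 h those were the urea cycle and amino acid list (10 of 15 members more positive in kidney, 13 when adjusted over the list alone, median 1.102, adjusted p = 7.05e-07, adjusted p = 0.0169 with an estimated correlation), gluconeogenesis and glycogen (9 of 10, 9 when adjusted over the list alone, median 1.37, adjusted p = 2.15e-04, adjusted p = 0.0169 with an estimated correlation) and p53 targets (9 of 13 more positive in liver, 9 when adjusted over the list alone, median -2.53, adjusted p = 1.38e-06, adjusted p = 0.0169 with an estimated correlation). In the urea cycle and amino acid list, however, 8 of the 15 members were at the floor in every kidney array. Among its 6 members above the floor in both tissues the median was 1.76, and the call was lost with an estimated correlation (adjusted p = 3.32e-04 with the preset one, 0.0557 with an estimated one). The other calls at 24 h remained with that restriction (adjusted p = 0.0318 for both, with an estimated correlation). At 48 h it was gluconeogenesis and glycogen (4 of 10 more positive in kidney, 5 when adjusted over the list alone, median 0.78, adjusted p = 2.35e-04, adjusted p = 0.0311 with an estimated correlation). Ribosome biogenesis at 24 h was more positive in liver for 14 of 16 members (14 when adjusted over the list alone, median -2.05, adjusted p = 8.47e-10, adjusted p = 0.0618 with an estimated correlation). Cholesterol synthesis was less negative in kidney for 13 of 16 (14 when adjusted over the list alone, median 2.01, adjusted p = 7.05e-07, adjusted p = 0.262 with an estimated correlation). Acute phase genes were more positive in kidney for 9 of 22 at 24 h (10 when adjusted over the list alone, median 1.47, adjusted p = 9.94e-05, adjusted p = 0.236 with an estimated correlation) and for 9 of 22 at 48 h (13 when adjusted over the list alone, median 1.09, adjusted p = 5.62e-06, adjusted p = 0.165 with an estimated correlation). In that list 7 of the 22 members were at the floor in every kidney array. Among the 13 above the floor in both tissues, 5 and 4 were more positive in kidney (medians 1.53 and 1.03, adjusted p = 0.00942 and 0.0171, and 0.301 and 0.265 with an estimated correlation). The restriction does not remove all background, as it keeps members with recurring kidney readings. Apcs, for example, read 3.777 in kidney 24 h B, 24 h C and sham C.

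Of 11662 genes tested in both tissues, 58 were higher and 109 lower in both at 24 h, against 46.8 and 54.4 for independent lists (Fisher's exact test, p = 0.0722 and 1.29e-13). Another 81 moved in opposite directions. The 109 included Idi1, Nsdhl, Sc5d and Ugt2b5, and the 58 included Lgals3, Tnfrsf12a and Cd14. Genes are not independent replicates, and the same mice may stand behind both tissues. The count of 167 was 2 without kidney sham B, 25 without sham A, 27 without 24 h B, 54 without sham C, 60 without 48 h B, 102 without 24 h A, 103 without 48 h C and 109 without 48 h A of the kidney. At 48 h, 11 genes were higher and 11 lower in both, against 9.3 and 6.2 (Fisher's exact test, p = 0.495 and 0.0594). Another 28 moved in opposite directions. That count of 22 was 0 without kidney 48 h B or C, 1 without kidney sham A, 2 without kidney sham B, 13 without kidney 48 h A, liver 48 h A or liver sham B, and 14 without kidney sham C or liver sham C.

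Within liver, 375 genes were higher and 279 lower at both times, against 134.8 and 71 for independent lists, and 59 moved in opposite directions. Dhcr7, Dbp and Bhlhe40 were among the lower genes. Both times share the 3 sham arrays, and part of the excess may come from the shared controls. Unchanged groups were simulated with independent genes and a simulated sham shared by both times. They gave a mean of 0 genes called at both times. The correlation of fold changes was 0.501 against 0.491 observed and the covariance 0.0571 against 0.347 observed. In both tissues a mean near 0 follows from the adjustment when nothing changes. It does not measure the part of the excess that comes from the shared sham. The liver count of 654 was 260 without sham B, 337 without sham C and 341 without 48 h A. Within kidney, 68 genes were higher and 70 lower at both times, against 3.4 and 5.2, with 1 in opposite directions. Serpina1b, Cyp4a14, Fgg and Scnn1a were among the higher genes and Slc51a and Idi1 among the lower. The simulated kidney covariance was 0.0285 against 0.0794 observed, with a mean of 0 genes called at both times and a correlation of 0.505 against 0.523. The kidney count of 138 was 6 without sham B, 9 without sham A, 11 without 48 h B, 21 without 48 h C, 40 without 24 h B, 62 without sham C and 82 without 48 h A.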

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

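The tests of a sham or 24 h liver under another label, of liver RNA in kidney and of the share of proximal tubule in kidney were chosen only after the result was seen, as were the list tests between the tissues and the restriction to genes above the floor in both, and the search for recurring readings. The results given here are those where the effect of GalN differed between times or tissues by a test of the difference itself, and the control-set values of the 1 liver array in which all 3 gaps between 3' and 5' sets lay above those of all sham livers.

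Between 24 h and 48 h in liver, 3355 genes differed. The changes were 7.30 for Cyp8b1, 7.19 for G6pc, 5.71 for Hectd2os, 5.64 for Fam47e and 5.41 for Lrit1, and -6.04 for Ddias, -5.00 for Epm2aip1, -4.66 for 9230114K14Rik, -4.55 for Eda2r and -4.38 for Plk2 (log2). In kidney 193 genes differed between the times, with 4.13 for Nusap1, 3.19 for Syn3, 2.69 for Igfbp1, 2.44 for Clec2h and 2.19 for 4931408D14Rik, and -3.58 for Mfsd2a, -3.18 for Slc25a25, -1.90 for Bdnf, -1.76 for Bcat1 and -1.75 for Asb11. The sizes for Cyp8b1, G6pc, Hectd2os, Fam47e, Lrit1, Ddias and Eda2r in liver are lower bounds, as are those for Nusap1, Bdnf and Asb11. At least 1 array of their lower group lay less than 1 above the floor. Liver array 48 h C adds to the sizes for Hectd2os, Epm2aip1 and 9230114K14Rik, so the bound for Hectd2os holds only with that array. At 24 h the responses of kidney and liver differed for 3778 genes, with 8.92 for Cyp8b1, 7.84 for Hectd2os, 7.17 for Lcn2, 6.74 for Cyp17a1, 6.72 for Hsd3b5, -6.44 for Cdkn1a, -6.10 for Cbr3, -6.04 for Ddias, -5.92 for Epm2aip1 and -5.86 for Tubb6 (kidney minus liver). At 48 h they differed for 1633 genes, with 5.28 for Cyp17a1, 5.11 for Lcn2, 5.02 for Saa2, 4.26 for Hsd3b5, 4.196 for Serpina1b, -5.30 for Psat1, -4.96 for Rps25, -4.67 for Mtnr1a, -4.60 for Bhlhb9 and -4.13 for Acot9. Cyp8b1, Hectd2os, Cyp17a1, Hsd3b5 and, at 48 h, Saa2 gave readings at or near background in the kidneys compared, so their differences restate the liver changes. Sham readings of Lcn2 (kidney), Cdkn1a, Cbr3, Ddias, Tubb6, Rps25, Mtnr1a, Bhlhb9, Psat1 and Serpina1b lie at the floor or recur in other arrays, as background does, so neither the exact size nor the rank of their differences is known. The Rps25 set read at or near background in every kidney array and may not report the main Rps25 transcript. The liver part of the Lcn2 differences was not called against sham, and the sham livers were unequal in Lcn2 and Saa2. Of the 15 and 12 gene lists that differed between the tissues at 24 h and 48 h, those that also differed with an estimated correlation, or were called in opposite directions in the tissues, had these medians: acute phase (1.47), urea cycle and amino acids (1.102), gluconeogenesis and glycogen (1.37) and p53 targets (-2.53) at 24 h, and acute phase (1.09) and gluconeogenesis and glycogen (0.78) at 48 h. With an estimated correlation the acute phase list was not called (adjusted p = 0.236 and 0.165). The urea cycle list lost that call among members above the floor in both tissues (adjusted p = 0.0557).

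For comparisons of 3 arrays with 3, the 10 splits of the arrays are too few for a share under 0.05. The real count and the highest of the other splits were 3966 and 2 genes for liver at 24 h (1 of 10 splits as large), 1228 and 2 for liver at 48 h (1 of 10), 3355 and 3 between the times in liver (1 of 10), 637 and 1 for kidney at 24 h (1 of 10), 323 and 2 for kidney at 48 h (1 of 10) and 193 and 3 between the times in kidney (1 of 10). For lists they were 13 and 15 in liver at 24 h (2 of 10 as large), 15 and 9 in liver at 48 h (1 of 10), 6 and 6 in kidney at 24 h (3 of 10) and 8 and 6 in kidney at 48 h (1 of 10). The median of the other splits was 10, 6, 3 and 4 lists in that order, so mixed labels also give list calls.

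With 100 regroupings, a share under 0.05 can be reached for the counts that join comparisons. Mixed labels within 1 tissue gave at most 2 genes against sham, so overlaps near 0 were largely set in advance for them. A low share therefore says only that the labels carry some effect. Whether tissues share or differ is not tested by them. The difference between tissues was reached by 1 of 100 at 24 h (3778, highest other 3460) and by 1 of 100 at 48 h (1633, highest other 1049), and those highest others kept the liver labels and mixed those of kidney, so much of each count arises from the liver response alone. Genes called in both tissues gave 1 of 100 at 24 h (167, highest other 0) and at 48 h (22, highest other 0). Exchanging sham and treated labels in kidney alone, not among the regroupings drawn, would give the 81 and 28 genes that moved in opposite directions. At 48 h that exceeds the real count. At 48 h the overlap was not beyond that of independent lists (Fisher's exact test, p = 0.495 for higher and 0.0594 for lower genes). Genes called at both times gave 1 of 100 in kidney (138, highest other 5) and 2 of 100 in liver (654). There the highest other, 1826, put the sham label on the 3 livers of 24 h, which points to a structure of the samples, the distance of those livers from the other 6.

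Serpina1b, Lcn2 and Fgg, transcripts of plasma and acute phase proteins, rose in kidney at 24 h, and RNA from liver in the kidney samples could raise them. The rise of Serpina1b would need 0.559% of liver RNA. At that share, 10 of 18 hepatocyte plasma transcripts lay more than 1 (log2) below the level needed, Apoa1 by 5.56, Ahsg by 5.36 and Alb by 1.55, which argues against this source. An effect of GalN on kidney expression stays open and was not tested separately.

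Liver array 48 h C stood apart from A and B. Its gaps between 3' and 5' control sets were 2.56 for actin, 0.81 for Gapdh and 4.96 for pyruvate carboxylase, above the highest sham values of 1.86, 0.332 and 3.80. Liver 24 h B and C exceeded them for actin (1.91 and 1.95), and 24 h C for Gapdh (0.345), but not for all 3. The SD of its deviations among probe sets of 1 gene was 0.47, 1.40 times that of the next liver array (0.337 in 48 h A), which is consistent with RNA or array quality of that array. Of 1599 genes called without it, it lay nearer to A and B than to sham for 62%, which decides nothing between a wrong label and a weaker response. On a scale from the sham mean (0) to the mean of A and B (1) it lay at 0.707, against 0.08 to 0.158 for sham livers held out in turn. From the 24 h mean it lay at 0.987, against 0.015 to 0.145, so the values argue against a sham or 24 h liver under its label. A test run before these, on genes beyond all arrays of the other group (77.2% and 86.5%), needed 112.8% and 99.7% and so could hardly exclude either. A mouse from outside these groups cannot be told apart from a weaker response, and a biological difference of that mouse was not tested.

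Distal nephron markers were higher as a list in kidney at 24 h with camera's preset correlation, with 3 of 17 called, but not with an estimated one (adjusted p = 0.572) or fry (adjusted p = 0.0664). A lower share of proximal tubule in the samples could raise them. That would raise markers of other kidney cells alike, but the median change was 0.689 for 17 distal nephron members and 0.02 for 48 podocyte, endothelial, macrophage and matrix members. The difference was 0.669 (bootstrap SE 0.247), but that SE treats list members as independent, with 3 arrays per group. Some of the 48 read near background in kidney, such as Cd68 (2.35 to 3.06), where a changed share could hardly show. The test therefore does not decide on the share of proximal tubule. The proximal tubule list had a median of -0.086. A different share of medulla in the pieces taken and an effect of GalN stay open and were not tested.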

How the results depend on the processing

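The filter at a value of 5 and the restriction to genes above the floor in both tissues were chosen only after the data were seen. No call of a named gene, or of a list against sham, reversed. In kidney, however, the side with more genes turned after quantile normalization, at 24 h and at 48 h. The cause of a moved count was not tested unless the setting itself uses fewer arrays or another number of probe sets. For 231 named results, 4986 alternative values held 4442 with the same call, 517 that lost it, 27 that gained it and 0 reversed. Of those lost, 343 left out 1 array. Since 46.8% to 48.8% of values lie at the floor, changes of dim genes cannot be measured, and folds against the floor are lower bounds.

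Counts of genes that moved by more than 1.5 times were as follows. With all probe sets, which counts several sets per gene, liver gave 6504 at 24 h, 1843 at 48 h and 5270 between the times. Kidney gave 487 at 48 h and 366 between the times, and the difference between tissues 6307 at 24 h and 2535 at 48 h. Without a filter the counts were 769 (liver 48 h), 285 (kidney 24 h), 131 (kidney 48 h), 64 (kidney between the times), 65 and 9 (both tissues, 24 h and 48 h), 427 (both times, liver) and 50 (both times, kidney). The filter at a value of 5 gave 512 (kidney 48 h), 44 (both tissues, 48 h) and 214 (both times, kidney). Array weights gave 4728 (liver 48 h), 1245 (kidney 48 h) and 4537 (between tissues, 48 h). All 18 arrays in 1 fit gave 2492 (liver 48 h), 361 (kidney 24 h) and 198 (kidney 48 h), and only the 6 arrays compared gave 757 (liver 48 h), 79 (kidney 24 h) and 24 (kidney between the times). The rank product test gave 597, 285 and 477 in liver (24 h, 48 h and between the times) and 180 in kidney at 24 h.

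With the array letter as a block, the counts were 605 (liver 48 h), 143 (kidney 24 h), 49 (kidney 48 h), 4 (kidney between the times), 35 and 5 (both tissues, 24 h and 48 h), 351 (both times, liver) and 15 (both times, kidney). Within a tissue, correlations of residuals show no pairing by letter: 0 of 9 with the same letter and 3 of 18 with different letters exceeded 0.1 in liver, and 1 of 9 and 5 of 18 in kidney. Between the tissues 2 of 9 and 0 of 18 did (means 0.073 and -0.036), so whether a letter marks 1 mouse across organs stays open. With the animal as a random block the correlation was 0.051. Lists shifted were 0 in all 4 comparisons with sham with an estimated correlation, and 20 (liver 24 h) and 0 (kidney 48 h) with fry.

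Leaving out 1 array at a time gave 2834 to 4652 genes for liver at 24 h, 448 to 1599 for liver at 48 h, 2581 to 3466 between the times in liver, 15 to 669 for kidney at 24 h, 29 to 469 for kidney at 48 h, 1 to 162 between the times in kidney. Between the tissues it gave 3171 to 4438 and 1140 to 2079 at 24 h and 48 h. Lists ran from 13 to 15, 13 to 17, 4 to 8 and 6 to 9 (liver 24 h and 48 h, kidney 24 h and 48 h). Genes called in both tissues ran from 2 to 197 at 24 h and 0 to 29 at 48 h, and at both times from 260 to 963 in liver and 6 to 135 in kidney. The arrays behind the moved counts were liver 48 h A and sham A, B and C for liver at 48 h (604, 804, 448 and 595), kidney 24 h B, 48 h B and sham A, B and C for kidney at 24 h (115, 263, 109, 15 and 198), and kidney 48 h A, B and C and sham A, B and C for kidney at 48 h (168, 31, 45, 29, 42 and 181). Between the times in kidney they were 24 h B and C, 48 h A, B and C, and sham A and B (111, 26, 1, 15, 21, 76 and 53). Where an array is left out, the remaining 2 of its group carry the comparison.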

Other observations

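The genes named in this part were chosen after their values were seen, from lists fixed beforehand, and 0 further hypotheses were tested. In liver at 24 h the list of galactose and uridine nucleotide metabolism did not shift (6 of 18 rose, 5 fell, camera adjusted p = 0.785). Upp2 fell by 6.35, Gne by 3.19, Dhodh by 2.00, Galt, which exchanges galactose and glucose on uridine sugars, by 1.68 and Ugp2 by 0.54. Ctps changed by 2.90, Cad, of pyrimidine synthesis, by 2.65, Uck2, a uridine kinase, by 1.94, Ugdh by 1.11, Upp1 by 0.78 and Nme1 by 0.70, all higher (adjusted p from 3.82e-04 for Ctps to 0.0399 for Dhodh). Heat shock genes did not shift as a list with camera (adjusted p = 0.0582), though fry called it (adjusted p = 0.049), with Hspb1 (3.23), Bag3 (2.26) and Hsp90aa1 (1.66) higher. Atf3 (3.74), Klf6 (3.05), Myc (2.83) and Jun (2.57), stress-induced transcription factors, and Icam1 (3.74), an adhesion molecule, were higher too. Their lists did not shift with camera, unfolded protein response genes with 4 of 16 rising and 4 falling (adjusted p = 0.508), immediate early genes with 3 of 12 rising and 1 falling (adjusted p = 0.318) and NF-kB and inflammation genes with 3 of 11 rising (adjusted p = 0.222), though fry called the latter (adjusted p = 7.09e-04). Of cell cycle genes, Mcm2 (2.97), Mcm4 (2.72) and Mcm5 (2.40), of the replicative helicase, and Pcna (0.92) rose, while the list did not shift (adjusted p = 0.508). The coagulation list did not shift (2 of 11 rose and 5 fell, median 0.12, camera adjusted p = 0.508), with F7 and Proc falling by 1.26 and 0.96 and Thbd, thrombomodulin, rising by 2.13.

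In kidney, Aqp1, the water channel of the proximal tubule, was higher by 0.77 at 24 h and 0.84 at 48 h (adjusted p = 0.0223 and 0.0234). Slc22a2, an organic cation carrier, fell by 0.50 and 0.59. At 24 h Asns, asparagine synthetase, rose by 1.80 and Atf4 fell by 1.41, in a list that did not shift (1 of 16 rose and 2 fell, camera adjusted p = 0.884). At 48 h Hsd11b2, which inactivates glucocorticoid in the distal nephron, rose by 0.69, Cubn, an endocytic receptor, by 0.61, and Slc22a6, an organic anion carrier, fell by 0.55.

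The hybridisation control bioB was 10.16 ± 0.11, 9.82 ± 0.10 and 9.83 ± 0.34 in liver and 9.47 ± 0.038, 8.95 ± 0.11 and 8.92 ± 0.16 in kidney (sham, 24 h and 48 h). In liver at 24 h, as in kidney at both times, every treated array lay below every sham array. The 3' control set of Gapdh in liver was 14.94 ± 0.092 in sham, 15.03 ± 0.14 at 24 h and 14.30 ± 0.14 at 48 h. The first principal component held 53.3% of the variance in liver and 29.9% in kidney.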
